A study of Homo sapiens with 12 samples.

How the data were processed

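LNCaP cells, an androgen-responsive line derived from human prostate cancer, were transfected with a precursor of the microRNA miR-135b or with a scrambled precursor as control. Both were used at 20 nM, and RNA was taken 12, 24 and 36 h later. The 6 groups of treatment and time held 2 arrays each, 12 in all, and the series' design text calls the 2 arrays of a group biological repeats, numbered 1 and 2. With 2 repeats per group the number of arrays limits the precision of every value.

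The deposited table of non-normalized values holds, per the file headers, the signal intensity of 47323 probes on a linear scale and a detection p-value for each probe and array. The values show no background subtraction, with array medians between 99.0 and 115 and no value below 0. GenomeStudio 2010.2 and lumi 1.8.3 are named in the submitters' processing notes, without their roles. A second deposited table holds the authors' processed log2 values of the same arrays. All 12 of its columns had a median of 6.736 and a single distribution, so they had been quantile normalized. Its scale was settled by setting each column against log2 of that array's non-normalized signal, where the slope lay between 0.962 and 1.03 and r was at least 0.9998. The values are not centred per gene, and whether any background correction came before is not given in the sources used here.

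The non-normalized intensities were background corrected with the normexp model of limma 3.58.1 in R 4.3.3. Negative control levels were inferred from the detection p-values, an offset of 16 was added, and quantile normalization and log2 followed. Probes with a detection p under 0.01 on at least 2 of the 12 arrays were kept, which left 19161. The platform annotation used here gives 30113 probes 1 gene name and 8 several names, and 17202 have no name in it. Old symbols were updated through a RefSeq gene table, used for names alone, since the array files name no genome build and coordinates are therefore not given. Probes with 1 name were used, and each gene was represented by its probe of highest mean over all arrays, which gave 11238 genes. For some named genes another kept probe that differs is given beside it. Between 15967 and 17856 probes were detected per array, or 33.7% to 37.7%. Replicate arrays correlated at r between 0.9804 and 0.9901 over the kept probes, arrays of different groups at 0.9709 to 0.993, and no arrays held identical signals.

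A linear model with 6 group means was fitted to all 12 arrays with lmFit and eBayes, with 6 residual degrees of freedom. Contrasts were miR-135b against control at each time, their mean over the 3 times, the effect at 36 h minus that at 12 h, a moderated F test of any difference between times, and control cells at 36 h against 12 h. All tests were two-sided, and an adjusted p is limma's with Benjamini-Hochberg adjustment over the genes tested, with 0.05 as the threshold. A log2 fold change is given with the standard error of the fit. The offset shrinks the fold changes of dim genes, while the background correction itself widens fold changes. The median of the reported miR-135 targets, given below, was -0.32 with that correction and -0.15 without it. Where a probe was detected on no array of a group, a fold is given as at least N-fold, from the mean of the brighter group against the higher of the lowest detected signal and the probe's own signal on each dim array.

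Whether the repeat numbers pair the arrays was checked from the deviations of arrays from their group means. Treated and control arrays of the same number and time correlated at 0.46 to 0.58 in 3 of 3 comparisons, above the 0.1 set as the limit, and those of different times at -0.1 to 0.31. The numbers were therefore taken to pair treated and control arrays within a time. The main fit stayed without the pairing, as planned, and a fit with a replicate block within each time, with 3 residual degrees of freedom, is given beside a result where it changes the call or moves a count by over 1.5 times. That fit has no contrast between times in control cells. The limit was set beforehand, but the correlations and the counts of both fits were first seen together.

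The 22 gene lists, the rule for named genes and the main alternatives were chosen before the data were examined. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 22 lists within a contrast. The same test with a correlation estimated from these arrays, and fry, were alternatives. The lists were reported miR-135 targets, androgen-induced and androgen-repressed genes, hypoxia-induced genes, G1/S and replication genes, G2/M genes, targets of p53, of WNT, of BMP and TGF-beta and of YAP/TAZ, interferon-stimulated genes, stress response genes, cholesterol synthesis, lipogenesis, apoptosis regulators, small RNA machinery, and markers of neuroendocrine, luminal, mesenchymal, basal, fibroblast and leukocyte type.

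Genes are named by these rules. HIF1AN and every measured reported target were named. 1 further gene of this first rule is not reported here. For the mean of 3 times these were the 10 largest rises and the 10 largest falls past the threshold in genes whose treated and control arrays did not overlap at any time. For each time they were the 5 largest rises and falls past the threshold without overlap. For contrasts between times they were the 3 largest of each direction past the threshold, or else the 5 smallest p. For each list they were up to 4 members of largest change, and not all of those that passed in neither fit are printed. A planned test of genes with a miR-135 seed site was not run, because no transcript sequences were used here.

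The fit was tested on simulated arrays for the 11238 genes, with 200 changed genes. In the mean of 3 times 85 of 100 genes changed by 1 on the log2 scale were called, and 47 of 100 changed by 0.5. At 36 h these were 43 and 3 of 100. Of the 11038 unchanged genes beside them 11 were called in the mean of 3 times and 6 at 36 h. No gene was called in simulated arrays without any change. The simulated noise was independent between arrays, without the differences that real repeats share. These rates are therefore not the error rates of the real arrays. Alternatives were other background corrections and offsets, the authors' processed values, median scaling, other detection filters, other ways to combine probes, replicate blocks, other variance models, array weights, fits of 1 time alone, an additive model, stricter thresholds and leaving out each array in turn.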

Results

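Gene expression was measured on 12 Illumina arrays of LNCaP cells, 2 for each combination of miR-135b or scrambled precursor with 12, 24 or 36 h of incubation. The series title names its question, the effect of raised miR-135b on the expression profile of these cells. The arrays read messenger RNA and not the transfected mature microRNA. The probe for its host transcript, MIR135B, was detected on 1 of the 12 arrays, so the transfection itself cannot be checked from these values. Between 15967 and 17856 probes were detected per array, and the median SD between repeats of a group was 0.121 to 0.164 on the log2 scale.

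Over the mean of the 3 times, 221 genes rose and 316 fell in miR-135b cells, of 11238 tested. Among the larger falls were the polycomb group gene SCML2 at -1.42 ± 0.09 (log2 fold change ± SE) and the potassium channel gene KCNMA1 at -1.24 ± 0.15. CPLX1, a complexin that acts in vesicle fusion, and PPP1R12B, a myosin phosphatase subunit, had fitted values of -1.75 ± 0.12 (adjusted p = 0.000103) and -1.45 ± 0.17. They were detected on 1 and 2 of the 6 treated arrays and on 6 of the 6 control arrays, so these values depend on signal near background and are not bounds. ZNF385B fell by 1.20, APTX, a DNA end-processing enzyme, by 1.12, the forkhead factor FOXN3 by 1.10, and the channel subunit KCNS3 and PNKD by 1.07 each. The mitochondrial ribosomal gene MRPL16 fell by 1.09. The other kept probe of PNKD read -0.15. The largest rises were those of LIAT1, at 1.44 ± 0.08 (adjusted p = 5.41e-05), the small GTPase gene RAB36, at 1.37 ± 0.11, and C12orf76, at 1.35 ± 0.07. RSPH1, which encodes a radial spoke protein of motile cilia, rose by 1.22 ± 0.11. C2orf15 and GGACT rose by 1.16 each, BBOF1, a basal body gene, by 1.15, the smooth muscle actin gene ACTA2 by 1.14, FBXO15 by 1.01 and the ciliary transition zone gene TMEM231 by 1.01. All 20 genes also passed with the pairing. Most effects were smaller: the median was 0.51 among rises and -0.50 among falls, and 11 rises and 13 falls reached 2-fold. The paired fit called 573 rises and 733 falls, among them 536 of the 537 genes.

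**Figure D1:**
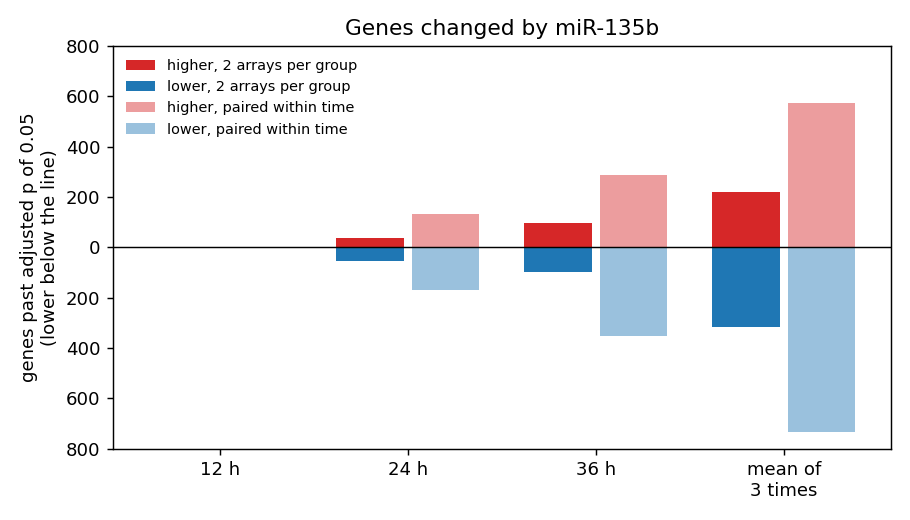
Genes past an adjusted p of 0.05 at each time and in the mean of the 3 times, higher in miR-135b cells above the line and lower below it, without (dark) and with (pale) pairing of repeats within a time. The counts at 12 h, 4 and 5, are too small to see at this scale, and those in the mean of 3 times are 221 and 316 without pairing.

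At 12 h, 4 of 11238 genes changed. C12orf76 rose by 1.04 ± 0.12, CPLX1 fell by 1.72 ± 0.21, SCML2 by 1.26 ± 0.16 and FOXN3 by 1.04 ± 0.12, with adjusted p between 0.0374 and 0.0423. With the pairing 5 genes passed, these 4 among them. An unadjusted p under 0.05 was reached by 558 genes, against 562 by chance, and by 1287 with the pairing. No gene passed without either treated or either control array of 12 h.

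At 24 h, 36 genes rose and 55 fell. RAB36 rose by 1.75 ± 0.19 and LIAT1 by 1.68 ± 0.14, and GGACT, C12orf76 and RSPH1 rose by 1.58, 1.48 and 1.46. CPLX1 was at least 2.93-fold lower (adjusted p = 0.00911), being detected on neither treated array. SCML2 fell by 1.36, APTX by 1.29, KCNS3 by 1.27 and the copper transporter gene SLC31A2 by 1.23. The paired fit called 131 rises and 171 falls, with 90 of the 91 genes among them. Median scaling in place of quantile normalization gave 23 rises and 16 falls. Leaving out 1 of the 4 arrays of 24 h left between 2 and 5 genes.

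At 36 h, 98 genes rose and 100 fell. RSPH1 rose by 2.05 ± 0.19 (4.13-fold, adjusted p = 0.00228), RAB36 by 1.86 ± 0.19, ACTA2 by 1.84 ± 0.19 and BBOF1 by 1.70 ± 0.14. DRC3, which encodes part of the dynein regulatory complex of cilia, was at least 2.07-fold higher (adjusted p = 0.0216), with no control array above detection, and its other kept probe read 0.84 in the mean of 3 times. CPLX1 was at least 2.86-fold lower and PPP1R12B at least 2.49-fold lower. AKR1C2, an enzyme that inactivates dihydrotestosterone, fell by 1.68 ± 0.27, and signal from close relatives of its family was not told apart here. SCML2 fell by 1.64 ± 0.16, and the pyrimidine synthesis gene DHODH fell by 1.43 ± 0.25. The paired fit called 289 rises and 353 falls, all 198 genes among them. Leaving out 1 of the 4 arrays of 36 h left between 9 and 57 genes.

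**Figure D2:**
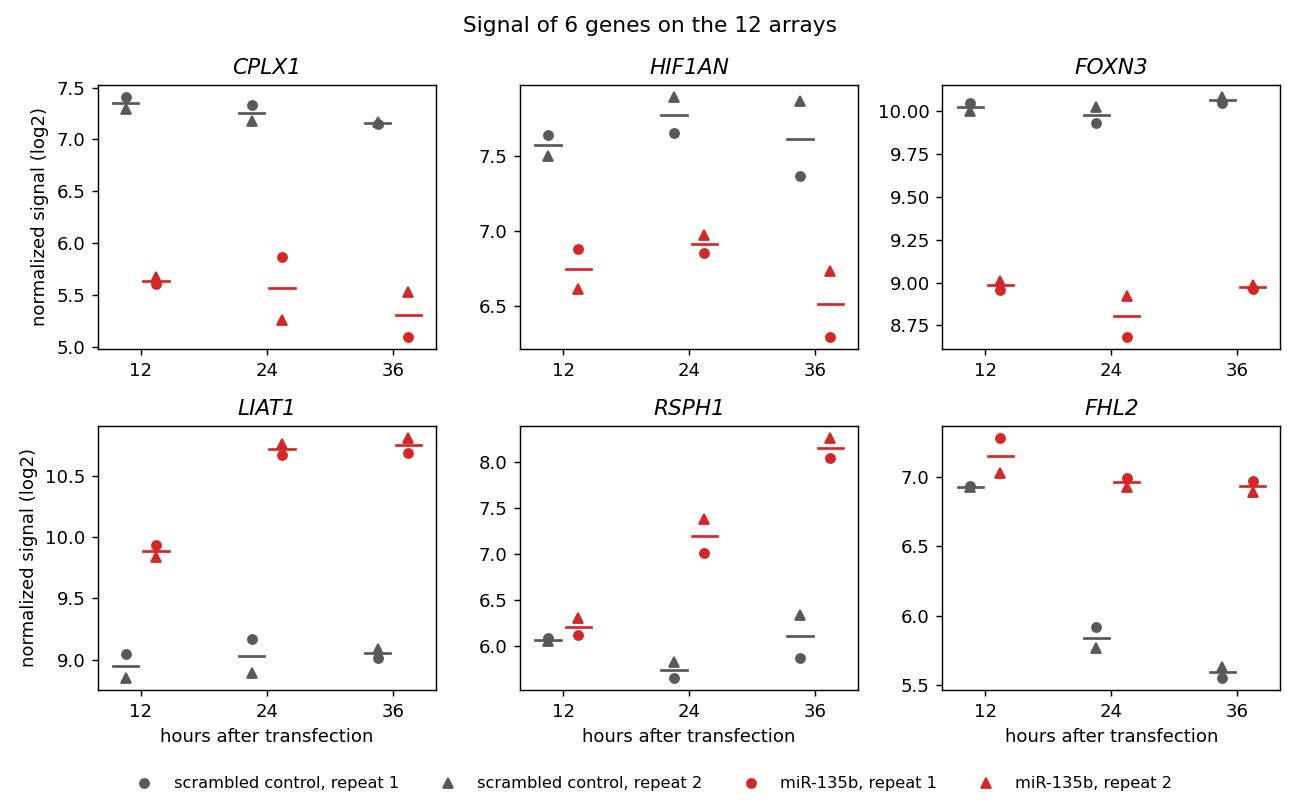
Normalized log2 signal of 6 genes on each array against hours after transfection, with circles for repeat 1, triangles for repeat 2 and a bar at the mean of each group. CPLX1, HIF1AN and FOXN3 lie lower and LIAT1 higher in miR-135b cells at every time. RSPH1 is higher by 0.14 at 12 h, 1.46 at 24 h and 2.05 at 36 h. FHL2 goes from 6.93 to 5.59 in control cells while treated cells go from 7.15 to 6.93.

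Among the 20 measured genes that other work has reported as miR-135 targets, 5 fell and 0 rose in the mean of 3 times, and 15 did not pass. Adjusted over the list alone, 8 fell. CPLX1, above, was among these falls, as was HIF1AN, which encodes an asparagine hydroxylase that restrains HIF1A, at -0.93 ± 0.12 (adjusted p = 0.00238). HIF1AN had a mean log2 signal of 6.75 ± 0.19 against 7.57 ± 0.10 in control at 12 h, 6.91 ± 0.08 against 7.77 ± 0.17 at 24 h and 6.51 ± 0.31 against 7.62 ± 0.35 at 36 h (SD, n = 2). The phosphatase gene PHLPP2 fell by 0.70 ± 0.10, the mineralocorticoid receptor gene NR3C2 by 0.63 ± 0.10 and the focal adhesion kinase gene PTK2 by 0.46 ± 0.08. Second probes of NR3C2 and PTK2 read -0.18 and 0.00, and PTK2 did not pass on the mean of its probes or with median scaling (adjusted p = 0.119 and 0.0745). SMAD5 at -0.47, SIAH1 at -0.41, KLF4 at -0.42 and RUNX2 at -0.32 passed with the pairing alone, at adjusted p of 0.0196, 0.0102, 0.0474 and 0.0203. RUNX2 was detected on 1 treated and 2 control arrays, and second probes of SIAH1 and KLF4 read -0.17 and -0.21. The others were JAK2 at -0.35, ROCK1 at -0.33, FOXO1 at -0.30, MTCH2 at -0.19, STK38L at -0.15, LATS2 at -0.14, GSK3B at -0.11, TXNIP at -0.04, BTRC at 0.03, ROCK2 at 0.08 and BMPR2 at 0.26. The list lay lower than other genes, with a median of -0.32 (camera adjusted p = 2.92e-06) and 17 of 20 members below 0. With an estimated correlation the adjusted p = 0.059, and 0.227 with the pairing as well. The median was -0.15 on the authors' processed values and without background correction, -0.20 with an offset of 50, -0.14 without the detection filter and -0.21 without the miR-135b array of 36 h, repeat 1, with the list past the threshold in each. By time the median was -0.32, -0.38 and -0.27 at 12, 24 and 36 h, and the effect at 36 h did not differ from that at 12 h past the threshold (camera adjusted p = 0.917). At 12 h the median was -0.18 on the authors' processed values and without background correction. At 24 h it was -0.16 without the detection filter, and the call was lost with an estimated correlation (adjusted p = 0.0693). The call at 36 h was lost with an estimated correlation (adjusted p = 0.198), without the detection filter (median -0.06, adjusted p = 0.285) and without the miR-135b array of 36 h, repeat 1 (median -0.17, adjusted p = 0.135) or the control array of 36 h, repeat 2 (adjusted p = 0.0512). ESR1 and APC were detected on no array.

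Of 40 measured G1/S and replication genes 8 fell, 0 rose and 32 did not pass in the mean of 3 times, and 26 fell adjusted over the list alone. The ubiquitin ligase adaptor gene DTL fell by 0.73 ± 0.12, and the helicase genes MCM3 and GINS2 by 0.51 each, while MCM5 at -0.48 passed with the pairing alone (adjusted p = 0.00777). The list median was -0.29 (camera adjusted p = 2.13e-14; adjusted p = 0.217 with an estimated correlation, and 0.276 with the pairing as well). It went from -0.04 at 12 h to -0.32 at 24 h and -0.52 at 36 h. Of 43 G2/M genes 1 fell, the kinesin gene KIF23, by 0.69 ± 0.11, with its other probe at -0.37, and 42 did not pass. FOXM1 at -0.43, KIF4A at -0.32 and CDK1 at -0.29 passed with the pairing alone, at adjusted p of 0.00636, 0.0316 and 0.0223. The G2/M median was -0.10 over the 3 times (camera adjusted p = 0.00133; adjusted p = 0.842 with an estimated correlation), and the call was lost without the miR-135b array of 24 h, repeat 2 (adjusted p = 0.0565). By fry, which tests against no change, the G2/M list did not pass over the 3 times (adjusted p = 0.23). At 36 h the G2/M median was -0.33 (camera adjusted p = 3.13e-10; adjusted p = 0.224 with an estimated correlation).

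**Figure D3:**
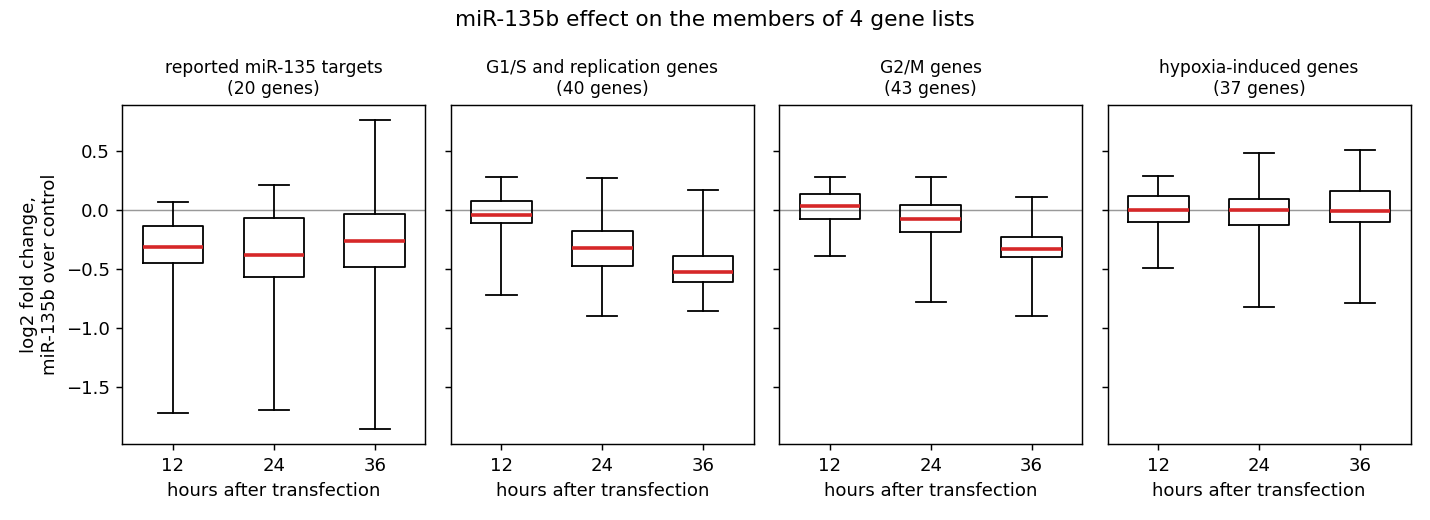
log2 fold change of miR-135b over control for the members of 4 gene lists at 12, 24 and 36 h, with boxes from the lower to the upper quartile, the median in red and whiskers to the lowest and highest member. The median of the reported targets lies at -0.32, -0.38 and -0.27, that of the G1/S genes goes from -0.04 to -0.52, and that of the hypoxia list stays within 0.01 of 0.

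HIF1AN restrains HIF1A, and LNCaP cells respond to androgen, so lists for hypoxia and androgen response were set beforehand. Of 37 hypoxia-induced genes 1 fell, the glycogen branching enzyme gene GBE1, by 0.66 ± 0.09, and 36 did not pass (median 0.00, camera adjusted p = 0.834). CA12 read -0.40 and passed with the pairing alone (adjusted p = 0.0203), ERO1A read -0.25 and P4HA2 0.23. Of 37 androgen-induced genes 2 rose, the retinal dehydrogenase gene ALDH1A3, by 0.57 ± 0.11, and IQGAP2, by 0.33 ± 0.07. MAF at 0.38 and PLPP1 at -0.32 passed with the pairing alone, at adjusted p of 0.0176 and 0.045. Of 11 androgen-repressed genes 1 rose, the butyrylcholinesterase gene BCHE, by 0.44 ± 0.10, which did not pass on the mean of its probes (adjusted p = 0.231; other probe 0.21), while PEG3 at -0.37 and ACKR3 at 0.36 passed with the pairing alone, at adjusted p of 0.0206 and 0.0210. The androgen lists had medians of -0.05 and -0.06 (camera adjusted p = 0.834 and 0.908).

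The remaining lists did not pass camera in the mean of 3 times, apart from the settings named here. Of 25 p53 targets SESN1 and SPATA18 rose, by 0.43 ± 0.09 and 0.41 ± 0.07, and TRIAP1 fell by 0.40 ± 0.08 (camera adjusted p = 0.464, and 0.0133 over every probe), and the cell cycle inhibitor gene CDKN1A read 0.53, with its other probe at 0.29, and passed with the pairing alone (adjusted p = 0.00979). Of 14 genes of the small RNA machinery DICER1, the enzyme that cuts microRNA precursors, rose by 0.73 ± 0.11 (adjusted p = 0.00661), with its other probe at 0.31 and an adjusted p of 0.0549 on the mean of its probes (list adjusted p = 0.485). Of 28 interferon-stimulated genes OAS3 and HERC5 fell, by 0.78 ± 0.12 and 0.50 ± 0.11 (list adjusted p = 0.834). Of 29 apoptosis regulators the survival gene BCL2L2 fell by 0.44 ± 0.07 (list adjusted p = 0.800). Of 14 WNT targets LEF1 fell by 0.29 ± 0.07 (list adjusted p = 0.896), and of 13 lipogenesis genes ELOVL6 fell by 0.34 ± 0.07 (list adjusted p = 0.834). Of 19 cholesterol synthesis genes 1 fell, ACAT2, by 0.31 ± 0.07, named after its value was seen, and 0 rose, with a median of 0.19 (camera adjusted p = 0.0783). With an estimated correlation the adjusted p = 0.936. With the pairing the list passed at the preset correlation (adjusted p = 0.0146, and 0.0212 at 24 h) but not at an estimated one (0.741, and 0.628 at 24 h). It also passed on the authors' processed values (0.047), without background correction (0.0478), without the detection filter (0.0362), over every probe (0.0133), with the repeat number as a block (0.0229) and in 5 of the fits without 1 array (0.0083 to 0.034). Passing with the pairing were also MSMO1 at 0.59, HMGCS1 at 0.40, IDI1 at 0.37 and INSIG1 at 0.36, at adjusted p of 0.0107, 0.0145, 0.0349 and 0.0439, although the other probe of MSMO1 read -0.09. No member passed among 14 BMP and TGF-beta targets, 13 YAP/TAZ targets and 30 stress response genes, with list adjusted p of 0.799, 0.908 and 0.799. Within these, TGIF1 read 0.25 and PDIA4 0.21, and CCN1 at 0.31, PTPN14 at 0.38, VLDLR at -0.36 and PPP1R15A at 0.31 passed with the pairing alone, at adjusted p of 0.0243, 0.0349, 0.0275 and 0.0451. The same held in other lists for TNFRSF19 at 0.34, ACLY at 0.23, CASP2 at -0.28, TNRC6A at 0.33 and MOV10 at -0.28, at adjusted p of 0.0144, 0.0446, 0.0283, 0.0389 and 0.0376, with the other probe of ACLY at -0.07. Some calls above lie near the threshold: of 12 fits without 1 array, 11 lost that of LEF1, 10 each those of BCHE, HERC5 and SESN1, 9 that of IQGAP2, 8 that of TRIAP1 and 6 that of ELOVL6. In the fits that lost the call, LEF1 read -0.263 to -0.318 and SESN1 0.405 to 0.464, so these 2 losses do not come from 1 divergent array. LEF1 also lost its call in 8 other settings, with an adjusted p of 0.052 on the authors' processed values and 0.241 with median scaling, BCHE in 5, IQGAP2 and ELOVL6 in 2 each (0.111 and 0.103 in the additive model, 0.104 and 0.135 with median scaling) and HERC5 in 1 (0.0779, median scaling). ALDH1A3 lost its call without the miR-135b array of 24 h, repeat 2 (0.0536).

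None of 20 luminal genes passed (camera adjusted p = 0.888). Few markers of other types were measurable: 4 mesenchymal genes, of which 0 passed, 3 neuroendocrine genes, of which STMN1 fell by 0.38 ± 0.08 (other probe -0.17, and adjusted p = 0.175 on the mean of its probes, with the call lost in 7 of 12 fits without 1 array), 1 basal gene, LAMB3 at 0.13, and 4 leukocyte genes, of which 0 passed. The camera adjusted p of these lists were 0.799, 0.639, 0.800 and 0.799. Of 4 fibroblast genes ACTA2 rose, TAGLN read 0.28 and passed with the pairing alone (adjusted p = 0.0282), and COL1A1 and FBLN1 read 0.02 and -0.07. The camera adjusted p of this list was 0.114, and 0.473 with an estimated correlation, 0.0271 for probes detected on all 12 arrays, and 0.0490 without the control array of 24 h, repeat 2. By fry, a test against no change rather than against other genes, the adjusted p was 0.00506, with ACTA2 the 1 member past the threshold. ACTA2 is shared with smooth muscle cells and with contractile states of other cells.

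Effects at the 3 times were set against each other. Across the 11238 genes, which are not independent replicates, the effects correlated at r = 0.35 (rho = 0.29) between 12 and 24 h, 0.29 (0.22) between 12 and 36 h and 0.57 (0.48) between 24 and 36 h. No array is shared by 2 times, but the calls at each time use 1 estimate of a gene's spread from all 12 arrays. A gene of small spread is therefore favoured at each time, and the lists of called genes are not independent. Of the genes called at 24 and at 36 h 32 rises and 46 falls were shared, against 0.314 and 0.489 for independent lists, and 0 went opposite ways. A difference between the effects at 36 h and 12 h was shown by limma for 0 genes, with or without the pairing, with 605 genes at an unadjusted p under 0.05 against 562 by chance, and 1557 with the pairing. The 5 smallest p belonged to RSPH1, BBOF1, DNAAF4, FHL2 and CFAP70, none past the threshold (adjusted p = 0.309). The differences were 1.91 for RSPH1, 1.28 for BBOF1 and 1.11 each for FHL2 and CFAP70. DNAAF4 was detected on 2 treated arrays, both of 36 h, and on 0 control arrays, so no value is given for it, and its other probe read 0.14 in the mean of 3 times. The F test over the 3 times also called 0 genes, with 452 at an unadjusted p under 0.05, and 1337 with the pairing. There the smallest p belonged to RSPH1, BBOF1, DNAAF4, FHL2 and UBE2J2 (adjusted p = 0.824).

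In control cells 2 genes changed from 12 to 36 h. FOS, an immediate early gene, fell by 3.65 ± 0.35 and FHL2, a LIM domain coactivator, by 1.34 ± 0.13 (adjusted p = 0.00872 for each). This fall of FHL2 did not pass on the mean of its probes (adjusted p = 0.065) or without 1 of the 4 control arrays of 12 and 36 h (0.0519 to 0.199), and that of FOS did not pass without the control arrays of repeat 1 at 12 h (0.158) or 36 h (0.199). In miR-135b cells FHL2 was 1.34 ± 0.13 above control at 36 h (adjusted p = 0.00245). This difference and the fall of FHL2 in control cells use the same 2 control arrays of 36 h, so they are not independent results. An unadjusted p under 0.05 was reached by 1523 genes, against 562 by chance. With the repeat number as a replicate block 68 genes passed. Androgen-induced genes lay higher at 36 h (median 0.31, camera adjusted p = 0.000437), as did androgen-repressed genes (median 0.44, adjusted p = 0.000264) and interferon-stimulated genes (median 0.14, adjusted p = 0.0374). Stress response genes lay lower (median -0.34, adjusted p = 1.26e-06), as did G1/S genes (median -0.18, adjusted p = 0.000437). With an estimated correlation none of these 5 passed, with adjusted p = 0.634, 0.496, 0.634, 0.634 and 0.634. By fry none passed either, with adjusted p = 0.386, 0.207, 0.267, 0.267 and 0.267. The call of the androgen-induced list was also lost without the control array of 36 h, repeat 2 (median 0.14, adjusted p = 0.108). Without the control array of 12 h, repeat 1, the medians of the androgen-repressed and G1/S lists were 0.29 and -0.11, both past the threshold. The call of the interferon list was lost without that array (median 0.06, adjusted p = 0.376), without the control array of 36 h, repeat 2 (median 0.07, adjusted p = 0.225), for probes detected on all 12 arrays (adjusted p = 0.374), on the authors' processed values (adjusted p = 0.0665), without background correction (adjusted p = 0.0663), over every probe (adjusted p = 0.0531) and with the repeat number as a block (adjusted p = 0.0662). With that block the cholesterol synthesis list passed here (adjusted p = 0.033, against 0.115 without), and with an estimated correlation and no block its adjusted p = 0.634.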

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

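The tests of culture time and of a divergent array below were chosen after the results were seen, while the comparison with other splits was planned. The limit for culture time was also changed after its value was known, and as first set, without regard to the single repeats, it argued against a later stage. The count of 537 genes in the mean of 3 times was set against other ways of splitting the 4 arrays of each time. Of 100 splits, drawn from 108, 1 gave as many genes, the real one, and the highest of the others gave 311. A chance split is therefore unlikely, at the resolution that 100 splits allow, but is not excluded. That highest split followed the repeat number, which shows that the 2 repeats differ in many genes. Among the 32 splits that part all 6 pairs, the highest other gave 67 genes against 537, and 296 against 1306 with the replicate block within time.

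By camera at the preset correlation, on the difference itself, the effect of miR-135b on 3 lists differed between 36 h and 12 h. By fry none of the 3 passed, with adjusted p = 0.064, 0.19 and 0.064 for the G1/S, G2/M and fibroblast lists. With the pairing and an estimated correlation the camera adjusted p were 0.435, 0.579 and 0.579. For the G1/S and replication list the median difference was -0.47 and 38 of 40 members were below 0 (camera adjusted p = 7.44e-18; adjusted p = 0.221 with an estimated correlation). For the G2/M list it was -0.33 with 43 of 43 members below 0 (camera adjusted p = 7.80e-12; adjusted p = 0.221 with an estimated correlation). For the fibroblast markers it was 0.36 over 4 genes (camera adjusted p = 0.0226; 0.0727 with the pairing; adjusted p = 0.221 with an estimated correlation), and the call was lost without the detection filter (0.926), without the miR-135b arrays of 12 h, repeat 2 (0.223) or 36 h, repeat 1 (0.297), and without the control arrays of 12 h, repeat 2 (0.12) or 36 h, repeat 2 (0.156).

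A divergent array was weighed for the 83 replication and mitosis genes. Their median difference of -0.406 stayed between -0.322 and -0.483 without each of the 8 arrays of 12 and 36 h, which argues against 1 array as the source. A later effective stage of the treated cultures would need a change of at least -0.196 in control cells from 12 to 36 h, taking 50% of the miR-135b effect of -0.391 at 36 h as the limit. The change there was -0.116 ± 0.028 (SE over genes), short of it. By repeat number it was -0.235 and -0.034, on both sides of the limit. Repeat numbers were not shown to pair arrays of 12 and 36 h, with a correlation of deviations of -0.04 for the controls. Arrays of 12 and 24 h correlated at 0.14 to 0.22 and those of 24 and 36 h at 0.25 to 0.31. Both ranges lie above the limit of 0.1, so repeats of these times share some differences. The SE over genes does not cover variation between arrays, so a later stage stays open. Stress response and androgen-repressed genes changed by -0.34 and 0.44 with time in control cells. Their miR-135b effects at 36 h read 0.07 and -0.06. Both measures use the control arrays of 36 h, with opposite sign, so noise in these arrays parts them. They therefore cannot decide whether treated cells followed such a shift. An effect of miR-135b on proliferation that grows with time stays open beside a later stage. With an estimated correlation neither list passes, so the difference itself may rest on a few independent changes shared by genes that vary together.

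Among 127 distinct named genes, 4 had treated arrays all above control at 1 time and all below at another, a difference that was not tested for this purpose. COL1A1 read -0.15 at 12 h and 0.26 at 36 h. ELOVL6 read 0.09 at 12 h, -0.55 at 24 h and -0.56 at 36 h. STK38L read -0.62 at 24 h and 0.23 at 36 h. UBE2J2 read 0.59 at 12 h and -0.68 at 24 h, and its other probe read 0.03 in the mean of 3 times.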

How the results depend on the processing

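The replicate block together with an estimated correlation, the exact test over pairs and the count without cilia families were chosen after seeing the data. The cause of the changes below was not tested, except that fits of 1 time alone and fits without 1 array have fewer arrays. The count at 12 h, 4, was 9 without background correction, 9 on the authors' processed values, 9 with trend and robust eBayes, 7 with an offset of 50, 2 without the detection filter, and 0 with median scaling, every probe tested, the repeat number as a replicate block or the 4 arrays of that time alone. The count at 24 h, 91, was 39 with median scaling, 302 with the replicate block within time, 146 with array weights and 0 from the 4 arrays of that time. The count at 36 h, 198, was 299 on the authors' values, 88 with median scaling, 333 with the repeat number and 642 with the time-wise pair as the replicate block, 106 with array weights and 0 from the 4 arrays of that time. The count in the mean of 3 times, 537, was 348 with median scaling, of which 337 were shared, 1306 with the replicate block within time, 213 at an adjusted p under 0.01 and 268 with a log2 fold change of at least 0.5 as well. The other planned settings kept it within 1.5 times, 753 with the repeat number as a block included. It was 481 without the cilia families. The count between times in control cells, 2, was 20 without background correction, 20 on the authors' values, 17 with an offset of 50, 14 for probes detected on all 12 arrays, 1 on the mean of a gene's probes, 39 with trend and robust eBayes and 68 with the replicate block. Both counts of effects that differ between times stayed at 0.

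Leaving out 1 array assumes that the lone array of a group varies like the other groups. It gave 0 to 1 genes at 12 h, 2 to 100 at 24 h, 9 to 159 at 36 h, 311 to 483 in the mean of 3 times and 0 to 4 between times in control cells. At 24 h the count was 3 and 5 without miR-135b repeats 1 and 2 of that time, 2 without either control, 52 without either miR-135b array of 12 h and 58 without either control of 36 h. At 36 h it was 49 and 57 without the miR-135b repeats 1 and 2 of that time, 31 and 9 without its controls, and 126 without either miR-135b array of 24 h. In the mean of 3 times it fell over 1.5 times without miR-135b repeat 2 of 12 h (325) and of 24 h (311), the controls of 24 h (356 and 355) and those of 36 h (345 and 334).

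In the mean of 3 times the list of reported targets kept its camera call (adjusted p 1.71e-06 to 1.25e-05 without 1 array) except with an estimated correlation (0.059) and with that and the replicate block within time (0.227). In an exact sign-flip test over the 6 pairs its mean shift was -0.37, below 0 in 6 of 6, with p = 0.0312, the smallest this test can give, which 4 other lists also reached (adjusted p = 0.137 over the 22 lists). In the mean of 3 times the androgen and hypoxia lists passed under none of the settings tried. The correlation of effects between 12 and 24 h was 0.248 without the detection filter and 0.241 to 0.351 without 1 array. Between 12 and 36 h it was 0.341 without background correction, 0.341 on the authors' values, 0.326 with an offset of 50, 0.202 without the filter, 0.338 for probes detected on all 12 arrays, 0.269 over every probe and 0.129 to 0.362 without 1 array. Between 24 and 36 h these were 0.637, 0.638, 0.618, 0.453, 0.641, 0.518 and 0.399 to 0.571. None of these correlations changed sign, and no call of a list or named gene was recorded in the opposite direction. Changes of sign among values that did not pass were not tallied. Over all list tests and settings outside the arrays left out, 786 values stayed on their side of the threshold, 46 lost a call and 12 gained one, and for named genes 1751, 63 and 79. Of 68 named values past the threshold 31 passed under every alternative. Slide as a block and the seed-site settings were not run. Dim genes limit the folds: their signal lies close to background, and detection was reached by at most 37.7% of probes.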

Other observations

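The families of cilia genes and the tests of their rise as a group and of early falls were chosen after the leading genes had been seen; the limit for ciliated cells was tightened after its value was seen, and the tests of brightness and culture time were set before their values were computed. Several of the largest rises belong to motile cilia. Of 42 measured genes of axonemal dynein, radial spoke, nexin-dynein and cilia-associated families, 16 rose, 0 fell and 26 did not pass in the mean of 3 times. Among these were RSPH1 at 1.22 ± 0.11, DNAAF19 at 0.99 ± 0.09, CFAP119 at 0.96 ± 0.09 and CFAP91 at 0.93 ± 0.12. The rises also count DRC3, DNAAF11, DNAI7 and DNAAF4, detected on only 4, 3, 3 and 2 of the 12 arrays. For probes detected on all 12 arrays 11 of 26 members rose. The dynein heavy chain genes DNAH1, DNAH2, DNAH6 and DNAH14 did not pass. Of 48 genes of intraflagellar transport, the BBSome and the transition zone 13 rose and 1, TMEM237, fell by 0.90 ± 0.07, with TMEM231 at 1.01, IFT140 at 0.80 ± 0.14 and IFT88 at 0.68 ± 0.10 among the rises. With the pairing 22 of these 48 rose and 2 fell, and of the axoneme families 20 rose and 1 fell. The median of the axoneme families was 0.14 at 12 h, 0.34 at 24 h and 0.51 at 36 h. Of 11 measured genes listed as regulators of ciliogenesis 1 rose, E2F5, by 0.64 ± 0.10, 1 fell, GMNN, by 0.72 ± 0.13, and 9 did not pass. The list does not part genes that promote ciliogenesis from those that restrain it. A fall in it therefore does not count against the rise of the families. Of these 9, MYB read -0.39, E2F4 -0.30, RFX2 -0.03 and RFX3 0.30. FOXJ1 was detected on no array.

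As a group the axoneme families lay higher than other genes (camera p = 1.19e-15; p = 7.69e-05 with an estimated correlation, and 0.00351 with the pairing as well), and their mean shift of 0.38 was above 0 in 6 of 6 pairs. Their median stayed between 0.17 and 0.35 under every setting tried. The members were fixed from genes that passed the detection filter. The setting without that filter therefore kept the same 42 genes and does not test its influence. Since the families were picked for their risers, this describes the pattern. A floor of dim probes is argued against, since the brighter members rose by a mean of 0.413 ± 0.084 (SE, 21 genes), the dimmer by 0.354 ± 0.086. In control cells the same families changed by a median of -0.063 from 12 to 36 h. In the 2 repeats the change was 0.022 and -0.104, short of the set limit of 0.253. Both measures use the control arrays of 36 h, with opposite sign, so noise in these arrays parts them. The comparison at 36 h therefore cannot decide alone. The median effect of 0.34 at 24 h shares no array with that control change, though no limit was set for it. It argues against treated cells of 24 h that ran ahead within the stages that control cells passed by 36 h. No control array lies beyond 36 h, so a stage later than that stays open for the treated cells of 36 h. Ciliated cells among the treated cultures stay open: 5 of 16 abundant ciliated cell transcripts were detected on a treated array at 36 h and 2 on both, too few transcripts to decide. Against such cells, RSPH1 among the 5 is itself part of the pattern, only 2 of the 10 outside the axoneme families were detected, TPPP3, SNTN and CIMIP1 were not, and CAPS at 0.49, SPMIP6 at 0.25 and AGR3 at -0.08 did not pass at 36 h. A rise of a ciliogenesis programme in cells given miR-135b is a hypothesis that these data may support and cannot settle, since no cilia were measured here.

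Falls and rises were also set against each other by time. Among genes called in the mean of 3 times, the median share of the 36 h effect already present at 12 h was 0.572 for 316 falls and 0.452 for 221 rises (permutation p = 0.00027). Without the cilia families the shares were 0.573 and 0.479 (permutation p = 0.0098). This measure restates the difference that prompted it, so it does not test whether falls come before rises. Genes are not independent, so the p understates the error.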
